A study of Drosophila melanogaster with 3 samples.

How the data were processed

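The series measured where a tagged transcription factor sat on the genome of Drosophila melanogaster embryos. Per the labels, the embryos were whole organisms aged 0 to 24 hours that carried a transgene for Cubitus interruptus (gene ci) fused to enhanced green fluorescent protein (eGFP), and chromatin sheared by sonication was precipitated with an antibody against GFP. ChIP-seq reads the precipitated DNA, so a peak is a place where more fragments were recovered than around it. The 3 samples were labelled as biological replicates 1, 2 and 3 of a single group. The labels named a control experiment, which was not analysed here, and the design held no comparison group.

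The authors deposited 14 peak lists on build dm6, per the notes filed with the samples. Each replicate had its own ranked list of candidate peaks and its own thresholded list. The rest of the lists covered the whole series and were made from the alignments of all 3 replicates together with a control file. A ranked list gives candidates matched between a pair of peak call sets, ordered by the irreproducible discovery rate (IDR), which estimates how likely a peak is to fail to recur. One of the series-wide thresholded lists was named conservative by the authors and served as the main list. The other 3 series-wide thresholded lists were used as alternatives and are numbered here by size, since which call sets each one compared was not given in the sources used here. The aligner, the peak caller and the IDR version were likewise not given in the sources used here.

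The score that the authors deposited for each peak is an IDR scaled to at most 1000. It equalled, within 1, the value computed from the −log10 IDR that the authors deposited in the ranked lists, for every candidate. All thresholded peaks had a score of at least 830, which is an IDR of 0.01. The thresholded lists held 2.52% to 3.23% fewer peaks than the ranked lists had candidates at that score, through a further step of the authors not described in the sources used here. The signal deposited by the authors is the peak caller's height for a peak, on a scale that was not given in the sources used here. It was therefore used only within a list, to rank peaks or to compare a peak with the list's median. The columns that the ranked lists give for the separate call sets were not used.

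Read counts were not given in the sources used here, so the depth per sample is unknown. The number of candidates and of peaks per list stands in its place, and confidence intervals on shares of peaks are Wilson intervals at the 95% level that cover counting error only. Peaks are not independent replicates of the experiment. Tests over peaks or genes describe these lists, and the spread between replicates is given wherever a value exists per replicate.

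Coordinates are 1-based on dm6. The sequence came from the Release 6 reference and the gene models from Ensembl release 115 (BDGP6.54), which use the same coordinates, and no peak ended beyond a reference sequence. Peaks on the 7 main chromosome sequences (2L, 2R, 3L, 3R, 4, X and Y) were analysed, and annotated transposons were set apart from the 18277 genes. A summit within 500 bp of any annotated transcription start site (TSS) was called promoter. Other summits were assigned in the order 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. The promoter share was compared with 1000 draws of equal size per chromosome from candidates that failed the threshold, two-sided.

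Peaks of different replicates were called shared when they overlapped by at least 1 bp. Chance sharing came from 1000 redraws of each replicate's peaks from its own candidates. For signal, the strongest candidate within 150 bp of a conservative summit was taken in each replicate. Relative signal is that value divided by the replicate's median over the 7321 conservative peaks with a candidate in all 3 replicates, and is given as mean ± SD over n = 3 replicates.

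The site searched for Ci was the Gli-type 9-mer GACCACCCA on either strand, within 100 bp of the summit. It was compared with a window of equal width 600 bp away on a randomly chosen side by an exact McNemar test, and with the 503 other orderings of its letters. The relation of the site to signal was tested with 100000 permutations. Another 19 motifs were tested in the same way, with Benjamini-Hochberg adjustment over all 20. A gene counted as having a peak when a summit lay in its body or within 5 kb of either end, a stretch called its territory. Each gene list was compared with 10000 random lists of the same size, matched on territory length in 10 classes and on biotype, two-sided, with Benjamini-Hochberg adjustment over the lists. Of 23 lists, the tRNA gene list was left out, because it held 295 genes where the annotation has 290 of that biotype, so that matched lists would draw the list itself. The symbols h, Dl, nos and dys were matched to their current names hry, Delta, nanos and dysf. Candidates around ci were counted in the 100 kb centred on the gene and ranked among the other windows of chromosome 4.

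The groups, tests, motifs, gene lists, the first set of alternatives below and the rule for named genes were fixed before the data were examined. The rule named ci and ptc, up to 25 members of the Hedgehog pathway and target lists by strongest peak, the gene with the nearest TSS at the 15 strongest peaks, and the 3 members of every other list with the strongest peak. The alternatives were the other series-wide lists, the stronger part of the conservative list by signal, peaks called in all 3 replicates, each replicate left out in turn (peaks shared by the lists of the remaining replicates), the maximum score, reciprocal overlap of 50%, summits within 100 bp, equal numbers of peaks, all candidates, chromosomes 2, 3 and X only, promoter distances of 200 and 1000 bp, protein-coding TSSs, uniform positions, motif windows of 50 and 200 bp, a mismatch, GC-matched positions, peaks away from promoters, territories of 1 and 10 kb, the nearest TSS, and a 40 kb window at ci. Added after the data were seen were the rotation of list membership along the gene order (1000 rotations, without matching on territory length), peaks with a signal of 60 or more, every alternative for the 19 other motifs, the following of motifs and lists that passed under any alternative, and the replicate left out in the count of peaks that a lone replicate called.

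The procedures were tested on simulated data. With the Ci site planted in 2% of 2000 simulated summits, the test called it in 50 of 50 runs, and in 0 of 50 runs without planting. The simulated summits were random positions, and the planted share was far above the 0.178% found at the real summits. These runs therefore do not show what the test could detect at that level. For gene lists of 40 members among 18277 genes, 192 of 200 lists were called after 50% of members were given a peak, and 9 of 200 lists without any change. Overlaps and promoter classes showed 0 differences from a direct comparison. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.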

Results

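ChIP-seq peaks were examined for Cubitus interruptus (Ci), the Gli-type zinc-finger transcription factor through which Hedgehog signalling acts, in whole Drosophila melanogaster embryos aged 0 to 24 hours. The embryos carried a ci-eGFP fusion, and 3 biological replicates formed a single group. The replicates held 88309, 89880 and 117847 candidate peaks, of which 6425, 4966 and 4541 were kept in the authors' thresholded lists. The mean was 5311 ± 988 peaks per replicate (SD, n = 3). The conservative list made from all replicates held 8431 peaks among 111202 candidates and had a median width of 344 bp. With no comparison group, the lists describe occupancy in this strain and do not measure a change.

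The first question was how well the replicates recovered the same sites. The strongest site, at the promoter of Ugalt, which encodes a UDP-galactose transporter, had a relative signal of 27.5 ± 2.05 (SD, n = 3). At ptc, which encodes the Hedgehog receptor Patched, the strongest peak had a relative signal of 2.93 ± 0.447, and at wg, which encodes the Wnt ligand Wingless, 1.16 ± 0.186. Of the 15928 peaks of the replicates' own lists, 8862 (55.6%) overlapped a peak in both other replicates. Redrawing peaks from the candidates gave a mean of 0.205% and at most 0.389% (permutation p = 9.99e-04, the smallest the draws can give). Pairwise, between 55.7% and 79.5% of a replicate's peaks overlapped a peak of another, and 95.4% to 98.8% overlapped a candidate of another. The base rate of overlap with candidates was high. Failing candidates of replicates 1, 2 and 3 overlapped a candidate of both other replicates in 53.8%, 52.5% and 40.2% of cases.

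Peak heights also followed each other between replicates. Of the conservative peaks, 7321 (86.8%) had a candidate within 150 bp in every replicate. Across these peaks, which are not independent replicates, Spearman's rho was 0.765 for replicates 1 and 2, 0.718 for replicates 1 and 3, and 0.736 for replicates 2 and 3. Pearson's r of log2 signal was 0.883, 0.807 and 0.825 for the same pairs. The median SD of log2 relative signal between replicates was 0.31, and 129 peaks (1.76%) had an SD above 1.

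The location of the peaks was compared with that of candidates that failed the threshold. Promoters held 4097 of the 8431 summits, or 48.6% (Wilson 95% interval 47.5% to 49.7%), against 15.2% of the candidates and 13.6% of uniform positions. The permutation p was 0.002, the smallest that the draws can give. Introns held 33.5% of the summits against 37.2% of the candidates, and intergenic sequence held 13.4% against 19.7%. Coding exons held 131 summits (1.55%) against 23.3% of the candidates, a ratio of 0.0667. Uniform positions lay in coding exons in 13.7% of cases, so the candidates were themselves rich in them and part of the gap comes from that background. In 3' UTRs the shares were 1.09% and 2.47% (Fisher's exact test, adjusted p = 1.93e-19), and in 5' UTRs they were 1.07% and 1.20% (adjusted p = 0.346). Uniform positions gave 4.36% in 3' UTRs and 0.745% in 5' UTRs, so for 5' UTRs the direction depends on the background. Annotated transposons held 9 summits, or 0.107%.

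**Figure D1:**
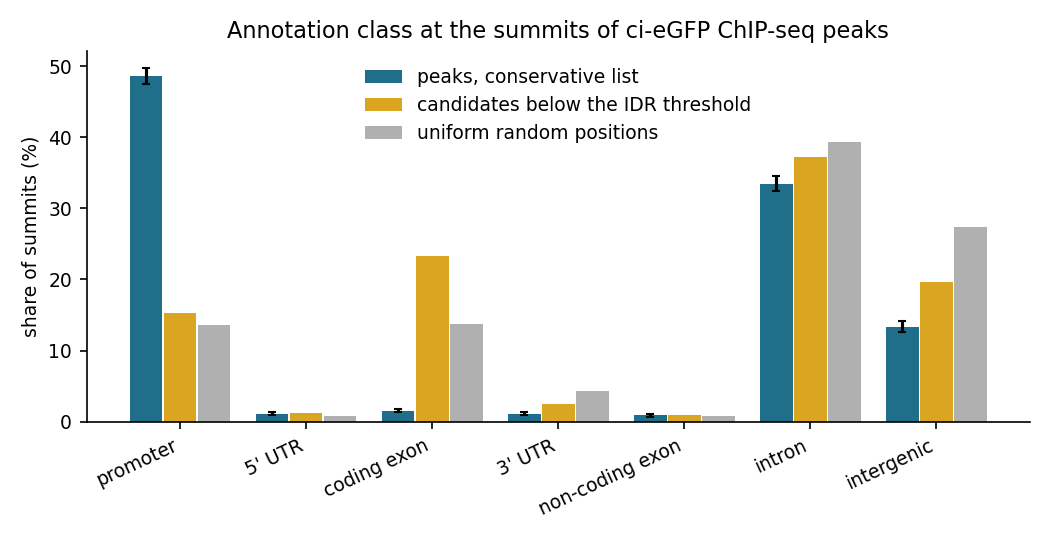
Share of summits (%) in each annotation class for the 8431 peaks of the conservative list (bars with Wilson 95% intervals), for candidates below the IDR threshold and for uniform random positions. Promoters held 48.6% of the peaks and 15.2% of the candidates, while coding exons held 1.55% and 23.3%.

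A promoter peak was present at 3926 of 13968 protein-coding genes (28.1%). On chromosome 4, the small and largely heterochromatic chromosome that carries ci itself, 3 of 80 genes (3.75%) had one. On chromosomes 2, 3 and X the share was 28.3% (two-sided Fisher's exact test, p = 2.62e-08). Chromosome 4 held 10 conservative peaks, or 7.42 per Mb, against 58.5 to 68.4 per Mb on the arms of chromosomes 2 and 3 and on X. Candidates were also sparse there, at 28.9 per Mb against 766 to 917 per Mb, so the comparison on chromosome 4 rests on few callable sites. The Y chromosome held 0 conservative peaks and 46 candidates.

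Most of the 15 strongest peaks lay at promoters. The strongest (X:2703717–2704048, signal 3753) had its summit 41 bp upstream of a TSS of Ugalt. The next was at CG14100 (3L:19590463–19590765, signal 3396, relative signal 24.6 ± 3.49). A peak at px, a wing vein gene, had a signal of 3040 (2R:22514156–22514451, relative signal 22.0 ± 4.11), and a peak at ph-p, which encodes the Polycomb group protein Polyhomeotic-proximal, had 2629 (X:2137206–2137506, relative signal 19.4 ± 3.52). Promoter peaks at CG18549, CenG1A, which encodes an Arf GTPase-activating protein, mRpL41, which encodes a mitochondrial ribosomal protein, and Art3, which encodes an arginine methyltransferase, had signals of 2702, 2551, 2372 and 2316. CG1888, Tcs5 and the non-coding gene lncRNA:CR31044 had promoter peaks with signals of 2311, 2205 and 2050. Intronic peaks lay at CG11050 (2L:6612382–6612969, signal 3088) and CG32772 (X:4910206–4910526, signal 2190). The peak nearest to CG13323 (2R:13035190–13035491, signal 2854) was intergenic, 11914 bp from its TSS and outside its territory. The 8th strongest peak (3R:31404498–31404811, signal 2607) lay 84 bp downstream of a TSS of PNPase, which encodes a mitochondrial exoribonuclease. It was also the strongest peak at the neighbouring Gprk2, which encodes a kinase that phosphorylates the Hedgehog signal transducer Smoothened.

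Whether the peaks carried the Gli-type site of Ci was asked next. The exact site GACCACCCA lay within 100 bp of 15 of 8431 summits (0.178%, Wilson 95% interval 0.108% to 0.293%) and in 12 of the flanks (0.142%). The difference did not pass the test (exact McNemar p = 0.701). Among 503 other orderings of its letters, 166 (33.0%) had at least as large a difference between summits and flanks. Allowing 1 mismatch gave 291 summits (3.45%) and 269 flanks (3.19%, exact McNemar p = 0.363). The stronger and weaker parts of the list, compared after the data were seen, lay on opposite sides, with 113 summits and 139 flanks among the 4215 strongest peaks (exact McNemar p = 0.111) and 178 and 130 among the 4216 weakest (exact McNemar p = 0.00552), with 63.4% and 27.8% of the other orderings at a difference as high. The strongest peaks with an exact site were 690 bp upstream of CG8635 (2R:8632517–8632779, signal 697), in intergenic sequence 13607 bp from the nearest TSS, that of Zasp52, a gene for a muscle Z-disc protein (2R:15762344–15762559, signal 645), and upstream of ptc (2R:8648791–8648998, signal 432). Others included a promoter peak at CycE, which encodes Cyclin E (2L:15746812–15747155, signal 153), and an intronic peak whose nearest TSS belongs to inv, a homeobox gene of the segment polarity class (2R:11493690–11494033, signal 110). These 5 were chosen after their values were seen.

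Presence of the exact site was not related to signal (Spearman's rho = -0.00332, permutation p = 0.766). In 4 classes of the list by falling signal, 4, 2, 5 and 4 peaks carried it. The ratio of summits to flanks was 1.25 and varied with the list, without passing the test in any. It was 5 without replicate 1 (5 summits and 1 flank, exact McNemar p = 0.219), 1.67 without replicate 2 (5 and 3) and 1 without replicate 3 (6 and 6). In series-wide list 1 it was 1.92 (25 and 13, exact McNemar p = 0.0730) and with 50 bp windows 2.25 (9 and 4, exact McNemar p = 0.267). The share lay below its flanks in series-wide list 3 (0.144% and 0.159%) and away from promoters (0.231% and 0.300%), and rho was 0.0164 to 0.0262 with any replicate left out. Flanks of the peaks away from promoters could themselves lie at promoters, so these windows are not alike. With 15 sites the interval is wide, and a small difference between summits and flanks was not detectable.

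Of 20 motifs, 7 were more frequent at summits than at flanks and 3 were less frequent (exact McNemar tests, Benjamini-Hochberg adjustment). The site of DREF, a promoter-binding factor of proliferation genes, lay at 3.06% of summits and 0.510% of flanks (exact McNemar, adjusted p = 1.54e-37). CTCF, an insulator protein, had its site at 2.35% and 0.439% (exact McNemar, adjusted p = 4.60e-27). Ohler motif 1, a core promoter element, was found at 2.13% and 0.451% (exact McNemar, adjusted p = 7.78e-23). The site of the GAGA factor, which keeps promoters open, was found at 7.91% and 4.28% (exact McNemar, adjusted p = 6.93e-23). At the 4334 peaks away from promoters, DREF was found at 0.415% of summits and 0.531% of flanks and Ohler motif 1 at 0.277% and 0.346%. Both calls were lost there and both directions turned. However, summits within 500 bp of a TSS were left out of that set, while flanks near a TSS were kept. For promoter motifs a loss is therefore built into the comparison and decides nothing. The CTCF site kept its direction there, at 2.61% of summits and 0.300% of flanks, and the GAGA site did so at 6.81% and 3.88%.

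Smaller differences were seen for 6 further motifs, each of which lost its call under at least 1 alternative. The E-box lay at 11.9% of summits and 9.65% of flanks (exact McNemar, adjusted p = 7.01e-06), but did not pass without replicate 1 (11.2% and 10.1%) or replicate 2 (11.4% and 9.89%), or away from promoters (9.32% and 8.61%, adjusted p = 0.459). The site of Opa, a Zic-type zinc-finger factor, lay at 1.55% and 1.01% (exact McNemar, adjusted p = 0.00472) and did not pass without replicate 1, 2 or 3 (1.26%, 1.26% and 1.45% of summits), with 50 bp windows or against GC-matched positions. The initiator lay at 19.9% and 18.2% (exact McNemar, adjusted p = 0.0134). It did not pass without replicate 1 (18.3%) or 2 (18.7%), with 50 bp windows or at a signal of 60 or more. Away from promoters, where only flanks could lie at promoters, it was less frequent at summits, at 17.0% against 19.9% (exact McNemar, adjusted p = 0.00402). The Caudal site was less frequent at summits, at 18.3% against 20.7% (exact McNemar, adjusted p = 3.08e-04), and the call was lost without replicate 1, 2 or 3 (20.6%, 20.4% and 18.6%), with the direction turned in the first pair. That call was also lost with 50 bp windows, against GC-matched positions and away from promoters. The Snail-type site lay at 6.80% against 7.98% (exact McNemar, adjusted p = 0.00844) and did not pass with 50 bp windows or away from promoters. The homeobox site of the Engrailed and Antennapedia type lay at 10.6% against 11.9% (exact McNemar, adjusted p = 0.0114), and turned in direction without replicate 1, 2 or 3 (13.8%, 13.6% and 12.02%), passing without replicate 1 (exact McNemar, adjusted p = 0.0451). It did not pass with 50 bp windows or at a signal of 60 or more.

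The sites of Ci, Zelda, AP-1, GATA, TCF, Su(H), Mad/Brinker, Grainyhead, the Twist-type E-box and the TATA box did not pass in the conservative list (exact McNemar, adjusted p from 0.0752 to 0.912). The TATA box, at 23.1% of summits and 22.1% of flanks there, passed in each list made without a replicate: 29.6% and 20.6% without replicate 1, 28.7% and 20.2% without replicate 2, and 26.5% and 21.9% without replicate 3 (exact McNemar, adjusted p from 1.75e-15 to 1.08e-05). It also passed among peaks with a signal of 60 or more (23.6% and 22.0%, exact McNemar, adjusted p = 0.0466). Zelda passed without replicate 2, as less frequent at summits (0.754% and 1.51%). The Mad/Brinker site passed away from promoters, at 8.93% and 6.32% (exact McNemar, adjusted p = 3.69e-05). Against GC-matched random positions the sites of AP-1, GATA, Grainyhead, the TATA box and Mad/Brinker passed as more frequent at summits, and that of TCF as less frequent (1.01% and 1.66%). With 200 bp windows Mad/Brinker and Grainyhead passed as more frequent, and Zelda (1.98% and 2.55%) and TCF (2.10% and 2.86%) as less frequent. Only the exact Ci site, Su(H) and the Twist-type E-box passed under none of the alternatives run.

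**Figure D2:**
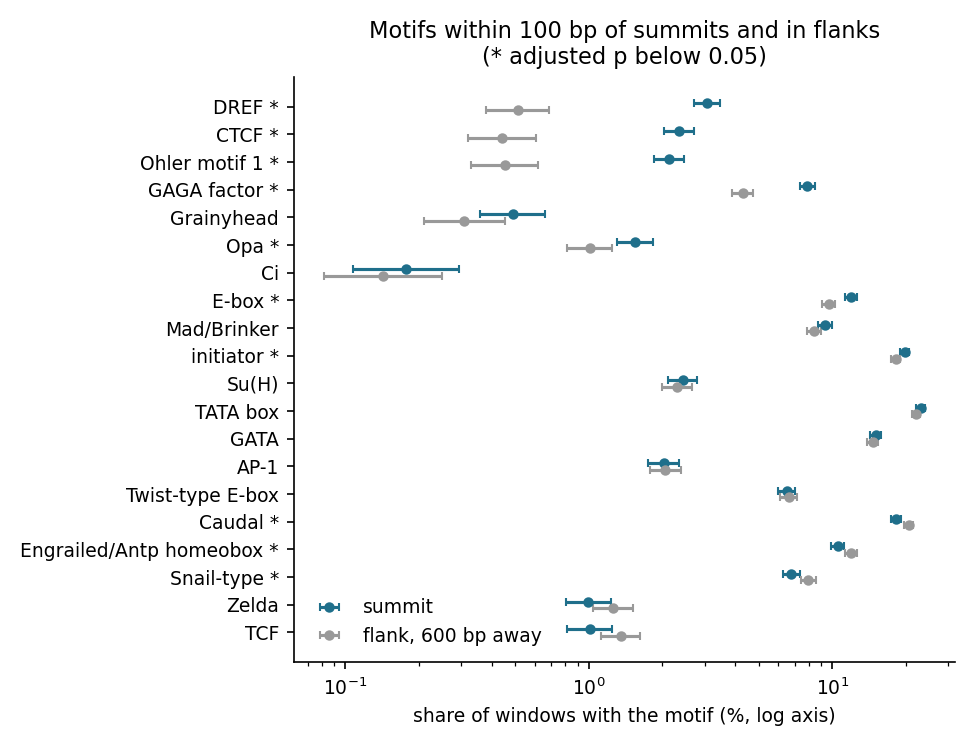
Share of windows (%, log axis) with each of 20 motifs within 100 bp of the summits and in flanks 600 bp away, with Wilson 95% intervals, where an asterisk marks an adjusted p below 0.05. DREF, CTCF and Ohler motif 1 lay at 3.06%, 2.35% and 2.13% of summits and at 0.510%, 0.439% and 0.451% of flanks, while the Ci site lay at 0.178% and 0.142%.

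The comparison most tied to the antigen was the presence of peaks at Hedgehog genes. Of 25 pathway genes, 22 had a peak in their territory against 17.8 ± 2.20 in matched random lists (mean ± SD, permutation p = 0.0842, adjusted p = 0.265), which did not pass the test. The ratio was 1.23 there and 1.14 to 1.61 over the alternatives, with adjusted permutation p from 0.0513 to 0.849. The nearest to passing were list rotation, which does not match on territory length (22 genes, ratio 1.46, permutation p = 0.0140, adjusted p = 0.0513) and peaks called in all 3 replicates (18 genes, ratio 1.61, permutation p = 0.0102, adjusted p = 0.0561). All 22 had in their territory a peak within 500 bp of a TSS, which was not always their own. Of 16 target genes, 11 had a peak against 11.6 ± 1.74 (permutation p = 0.939). No peak was found in the territories of ci, of Su(fu) and disp, an inhibitor of Ci and a Hedgehog release factor, or of the targets en, ara, bap, eya and ato.

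The gene ptc (2R:8649649–8665223), both a pathway member and a target, had 18 peaks in its territory. Several of these, with summits from 2R:8666098 to 2R:8670180, lay past the end of ptc, at a TSS or in introns of another gene. Its strongest peak lay 774 bp upstream of the gene start and held an exact Gli-type site at 2R:8648891–8648899. A further pair of exact sites lay at 2R:8648948–8648956 and 2R:8649014–8649022, and another in an intron at 2R:8657250–8657258, 56 bp from the summit of a weak peak (signal 71.5). A promoter peak 100 bp upstream of the gene start had a signal of 375 (relative signal 2.75 ± 0.642). Replicates 1, 2 and 3 called 17, 13 and 14 of the 18 peaks in their own lists, and 12 were called in all 3. The weak intronic peak with a site was called in none of the replicates' own lists.

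**Figure D3:**
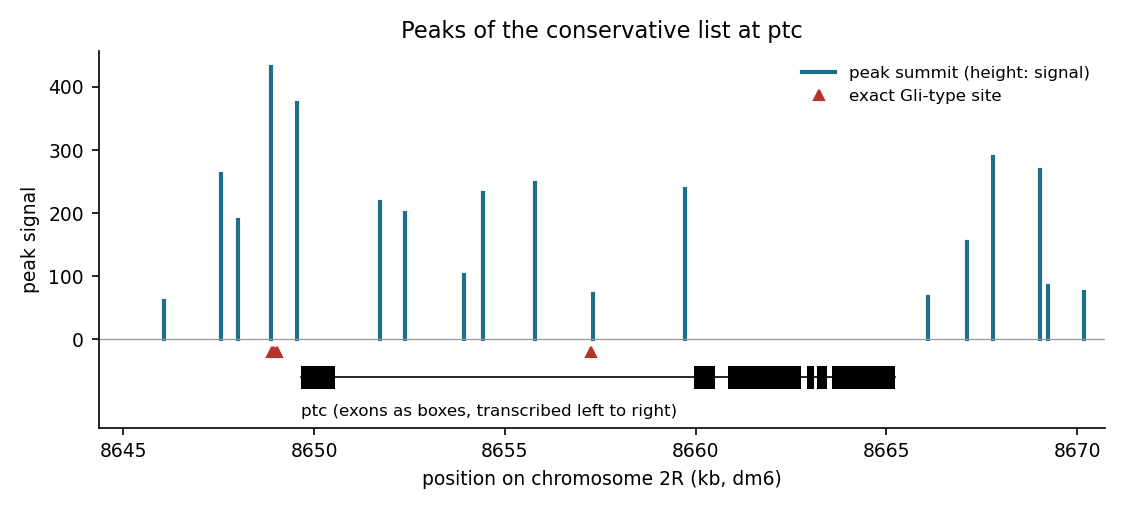
Peaks of the conservative list in the territory of ptc on 2R (kb, dm6), with lines at the summits whose height is the peak signal, exons as boxes and exact Gli-type sites as triangles. The highest of the 18 peaks, with a signal of 432, covers 2 of the 3 upstream sites.

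Other pathway genes had peaks of varied strength. The kinase genes gish, which encodes a casein kinase, and sgg, which encodes the fly GSK3, had promoter peaks with signals of 1702 and 764 and relative signals of 12.2 ± 2.94 and 5.20 ± 1.03. The kinase genes Pka-C1 and CkIalpha, whose products phosphorylate Ci, had peaks at their promoters with signals of 213 and 166. The glypican genes dlp and dally had 10 and 9 peaks, the strongest intronic, with signals of 442 and 246. Among the heparan sulfate synthesis genes, sotv, botv and ttv had strongest peaks with signals of 297, 289 and 192. The coreceptor genes boi and ihog had 306 and 278, smo, which encodes Smoothened, had 227, and cos, which encodes a kinesin-like scaffold, had 167. The gene shf, which encodes a secreted factor for Hedgehog spread, had a signal of 449, Cul3, a ubiquitin ligase gene, 201, and rasp, an acyltransferase gene, 143. The strongest peaks of botv, smo, cos, shf, Cul3 and rasp lay past the end of these genes, at a TSS of another gene. They were 2914 bp (rasp) to 8558 bp (shf) from the TSS of the gene named. Those of ihog and ttv also lay at a TSS of another gene, 1537 and 12190 bp from their own. The gene rdx, which encodes an adaptor for degradation of Ci, had 22 peaks, the strongest in an intron (3R:14012626–14012803, signal 438). Of 174 genes with a territory of similar length, 0 had as many peaks as rdx in the conservative list, 1 or 2 did in each other series-wide list, and up to 3 did in a single replicate's list or among the 4215 strongest peaks.

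Among the target genes, dpp, which encodes a BMP ligand, had its strongest peak in an intron (2L:2433543–2433727, signal 492, relative signal 3.36 ± 0.847). An intronic peak at vn, which encodes a neuregulin-like ligand, had a signal of 314 and a relative signal of 2.29 ± 0.0310. Peaks at the promoters of rho, which encodes an intramembrane protease, and wg had signals of 195 and 168. The strongest peaks of kn, a gene for a COE-type transcription factor, and CycE had signals of 279 and 216 and lay 26605 and 3016 bp from the TSS of these genes.

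Of 22 gene lists, 3 differed from matched random lists after adjustment. Ribosomal protein genes had peaks at 82 of 92 members against 48.4 ± 4.68, with the strongest at the promoters of RpL7 (2L:10200889–10201197, signal 1463), RpS27 (signal 1299) and RpL14 (signal 1125). Cuticle protein genes had peaks at 21 of 97 members against 50.4 ± 4.83, with the strongest at Cpr78Cc (signal 1664) and at the neighbouring Cpr76Ba and Cpr76Bb, which shared a peak (signal 498). Chemoreceptor genes had peaks at 48 of 185 members against 105 ± 6.59, with the strongest at Ir25a (signal 1716), Ir68b (signal 1083) and Gr5a (signal 590). The strongest cuticle and chemoreceptor peaks lay between 1608 bp (Cpr76Ba) and 3995 bp (Cpr78Cc) from the TSS of the gene named. Each permutation p was 2.00e-04, the smallest that the draws can give, and each adjusted p was 0.00147. Over the alternatives the ratio to matched lists ranged from 1.34 to 4.17 for ribosomal protein genes, from 0.217 to 0.682 for cuticle protein genes and from 0.172 to 0.661 for chemoreceptor genes, and each passed. For scale, 8326 of 13968 protein-coding genes (59.6%) had a peak in their territory.

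The other 19 lists did not pass the test, with adjusted permutation p from 0.246 to 1. Short lists had little room to pass upwards, since most matched genes already had a peak. With territories of 10 kb, all 18 EGFR and FGF genes had one against a matched mean of 14.7, and the adjusted permutation p was 0.268. For such lists a failure to pass decides little. Peaks lay at 19 of 22 Wnt pathway genes (matched mean 15.8), with the strongest at gro, dsh and fz (signals 786, 772 and 762). They lay at 15 of 18 BMP pathway genes (12.6), with the strongest at gbb, which encodes a BMP ligand (2R:23850261–23850541, signal 1682), Med (signal 1399) and Mad (signal 782). EGFR and FGF pathway genes had peaks at 17 of 18 members (13.4), with the strongest at aos, a gene for a secreted EGFR inhibitor (signal 938), Krn (signal 621) and aop (signal 615). Peaks lay at 15 of 20 Notch pathway genes (13.2), among them E(spl)m8-HLH and E(spl)m7-HLH, whose strongest peak was the one at gro, and neur (signal 609). JAK-STAT pathway genes had peaks at 6 of 8 members (5.77), with the strongest at chinmo, Socs36E and Stat92E (signals 459, 353 and 266). The strongest peaks of gbb, Med and Socs36E lay at a TSS of another gene, 1163, 5136 and 6940 bp from their own. That of dsh lay outside its body in an intron of another gene, 4342 bp from its TSS.

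Patterning and tissue lists were among these. Segment polarity genes had peaks at 11 of 16 members (matched mean 11.4), among them slp2 (signal 900) and nkd (signal 552), besides ptc. Pair-rule genes had peaks at 6 of 9 members (5.71), with hry at 202 and odd at 137 next to slp2. Gap genes had peaks at 4 of 11 members (7.31, permutation p = 0.0770, adjusted p = 0.265), with oc, cnc and knrl at 261, 252 and 169. Hox genes had peaks at 6 of 8 members (6.16), with Antp, abd-A and Scr at 265, 240 and 207. Neuroblast and neuron genes had peaks at 12 of 20 members (13.2), with elav, pros and Dr at 843, 464 and 326, and muscle and mesoderm genes at 12 of 16 (11.7), with tin, Mef2 and kirre at 854, 781 and 567. Tracheal genes had peaks at 7 of 8 members (5.89), with rib, sim and dysf at 632, 353 and 194. Gut genes had peaks at 7 of 9 members (6.32), with bowl, cad and fkh at 462, 384 and 360, and hemocyte genes at 8 of 12 (8.56), with ush, Hml and gcm at 542, 466 and 175. The numbers beside each gene are signals of its strongest peak. For pros, Mef2, cad and gcm that peak lay at a TSS of another gene, 1054 bp (Mef2) to 37170 bp (pros) from their own. For abd-A and Hml it lay outside the gene body in an intron of another gene, 4796 and 16543 bp from their own TSS.

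Housekeeping and germline lists gave mixed counts. Germline genes had peaks at 8 of 10 members (matched mean 6.70), where bam shared the peak of its neighbour RpS27 and otu and nanos had signals of 475 and 446. Cell cycle genes had peaks at 17 of 19 members (12.5, permutation p = 0.0448, adjusted p = 0.246), with CycB, fzr and PCNA at signals of 1342, 733 and 578. Proteasome genes had peaks at 24 of 48 members (26.3), with Prosbeta2R2, Rpn5 and Prosalpha4 at signals of 1452, 710 and 447. The strongest peaks of nanos, fzr, PCNA, Rpn5 and Prosalpha4 lay at a TSS of another gene, 1104 bp (PCNA) to 10531 bp (fzr) from their own. Those of otu and Prosbeta2R2 lay outside the gene bodies in introns of other genes, 3510 and 3993 bp from their own TSS. When list membership was instead rotated along the gene order, which keeps neighbouring genes together but drops the matching on territory length, 5 lists passed, adding the EGFR and FGF list (adjusted permutation p = 0.0220) and the cell cycle list (adjusted permutation p = 0.0352). The mean of the random lists was lower there, at 10.8 against 13.4 for the EGFR and FGF list and 11.5 against 12.5 for the cell cycle list.

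**Figure D4:**
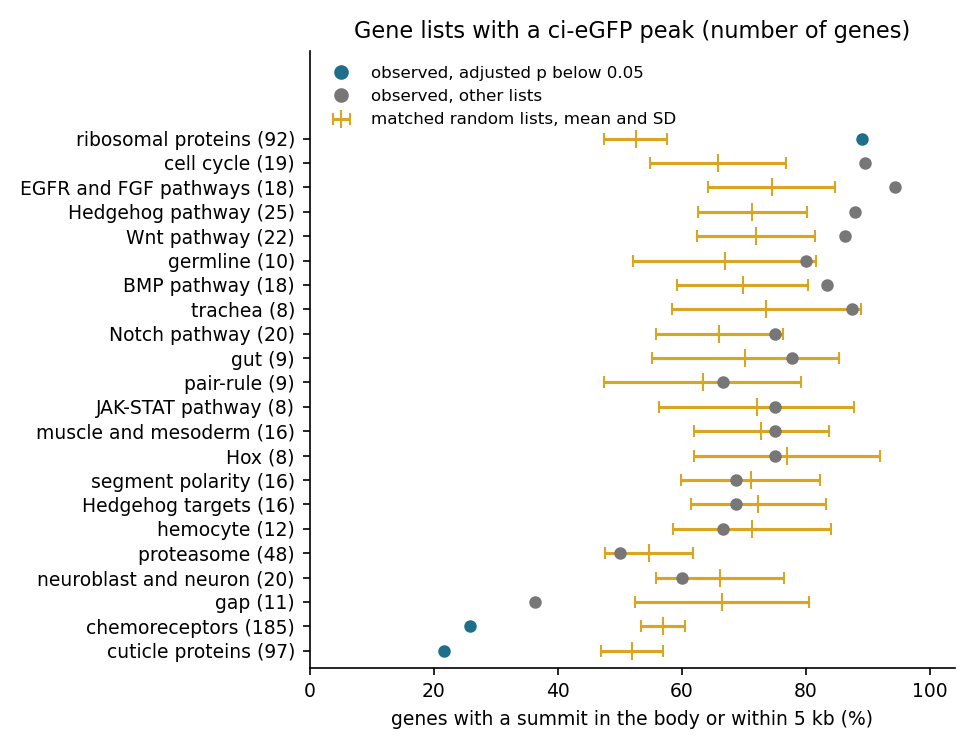
Share of genes (%) with a summit in the body or within 5 kb for 22 gene lists (points, number of genes in brackets) beside the mean and SD of matched random lists (bars). Ribosomal protein genes, with 82 of 92, lie above their matched lists, and cuticle protein genes (21 of 97) and chemoreceptor genes (48 of 185) lie below.

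The density of candidates was examined at the ci locus, which the transgene also carries. The 100 kb around ci (4:2376–102375) held 1, 3 and 0 candidates in replicates 1, 2 and 3, with a mean of 1.33 ± 1.53 (SD, n = 3). The median of the 12 other windows of chromosome 4 was 1.5, the highest was 22.3, and 7 were as high as the ci window (exact rank p = 1, with a smallest possible p of 0.154). No replicate's own list had a thresholded peak in the ci window. With so few windows the test could not pass a threshold of 0.05. The direction turned with a 40 kb window (mean 0.667, median of the other windows 0) and without replicate 1 (mean 1.5, median 1).

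Peaks called in a lone replicate were compared with peaks called in all 3. They made up 28.5%, 14.6% and 15.8% of the lists of replicates 1, 2 and 3 (mean 19.6% ± 7.75, n = 3), and 31.8%, 33.3% and 29.2% on average without replicate 1, 2 or 3. In replicate 3, 29.8% of such peaks lay at promoters against 50.1% of its shared peaks (Fisher's exact test, p = 4.20e-23). In replicate 1 the shares were 49.7% and 50.7% (Fisher's exact test, p = 0.514), and in replicate 2 they were 49.4% and 50.3% (Fisher's exact test, p = 0.648). By summits within 100 bp the direction turned in replicate 1 (50.6% and 49.7%) and in replicate 2 (51.5% and 49.7%), again without passing. Exact Gli-type sites lay at 6, 4 and 1 of the peaks of a lone replicate and at 5 of the shared peaks in each list, and no difference passed Fisher's exact test (p = 0.352, 0.0814 and 1).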

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

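For the Gli-type site, the mismatch over all peaks was among the alternatives fixed before the data were examined. Its split by signal was chosen after the results were seen. So were the tests of base composition and of Hedgehog genes for that site. The overlap of replicate 3 peaks with candidates of the other replicates, and the count of all candidates at ptc and rdx, were chosen then too.

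Peaks outside the 7 main chromosome sequences were left out of every comparison, and some lists held more of them than the 3 that a count of 0 allows. There were 4 in replicate 3, 4 in series-wide list 1 and 8 in series-wide list 3, and 0 in the other thresholded lists.

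The territories of ptc and rdx held more conservative peaks than those of other genes with a territory of similar length: 18 at ptc against a median of 2 and at most 13 among 901 genes, and 22 at rdx against a median of 4 and at most 20 among 174 genes. These counts take in neighbouring genes, and several of the 18 peaks lay past the end of ptc. The lead of rdx was seen in the conservative list and not in the others, since similar genes reached its count in each of the other series-wide lists (24, 19 and 17 at rdx, at most 27, 20 and 18 elsewhere) and among the 4215 strongest peaks (10, at most 12), while none reached that of ptc in these lists. After merging summits within 1000 bp, the count fell to 10 at ptc against at most 9 at similar genes, and to 19 at rdx against at most 15. Merging also joins distinct nearby sites, so the fall does not show that broad regions were split into neighbouring peaks. Splitting into summits within 1000 bp of each other does not account for the whole lead in the conservative list, since 0% of the similar genes reached either merged count. The margin left at ptc was narrow, and splitting at wider spacing was not tested. No replicate alone gave the peaks, as at most 1.72% of similar genes reached the count in any replicate. Extra copies or open mapping stay open, since neither count decides: 64.0% of the genes similar to ptc and 21.8% of those similar to rdx had as many failing candidates, which met the bound set beforehand, but a peak that passes leaves that count, while 9.88% and 5.75% had as many candidates in all, a count that replaced it and contains the peaks in question. Whether Hedgehog targets in general carry more peaks stays open: without ptc and rdx they held 24 peaks against 34.1 ± 10.3 in matched lists (permutation p = 0.338), which met the bound set beforehand (at or below the mean) by less than the spread. The test cannot decide in any case. The genes ptc and rdx were left out for their high counts while matched lists kept their highest genes, which biases the observed total downwards.

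The exact Gli-type site was about as frequent at summits as at flanks, at 15 and 12 of 8431 peaks, and at 5 and 1 of 3243 without replicate 1. Use of sites with 1 mismatch stays open over all peaks (upper bound of 1.29 for the ratio), among the 4215 strongest (113 summits and 139 flanks, upper bound 1.05), where 63.4% of the other orderings of the letters had a difference as high, and among the 4216 weakest (178 and 130, exact McNemar p = 0.00552, upper bound 1.78), where 27.8% did and the bound set beforehand was met but excludes nothing at that width. Base composition stays open too, since 33.0% of the orderings of the exact site differed as much and 15 sites are few, and the median ordering with at most 1 mismatch lay at 17 fewer summits than flanks among the strongest peaks and at 32 more among the weakest. Against GC-matched random positions, an alternative fixed beforehand, the exact site lay at 15 summits and 10 positions (exact McNemar p = 0.405). With so few sites that comparison does not decide either. Dilution by peaks elsewhere stays open as well: peaks at Hedgehog genes carried the exact site at 3 of 141 against 12 of 8290 others (Fisher's exact test, p = 0.00180) and a site with at most 1 mismatch at 7.80% against 3.38% (p = 0.00944), but without ptc, whose neighbouring peaks are not independent, the shares were 0.813% (p = 0.174) and 4.07% (p = 0.612). Indirect recruitment was not tested.

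Peaks called only in replicate 3 lay at promoters in 29.8% of cases against 50.1% of its shared peaks. Weighting the shared peaks to the same GC content gave 51.7% and to the same signal 56.4%, so neither property accounts for the gap. Of the peaks called only in replicate 3, 87.3% overlapped a candidate in both other replicates, against 40.2% of the candidates of replicate 3 that failed and 84.8% and 87.6% of the peaks of a lone replicate 1 or 2, so most were not absent there. Weak calls of a background kind stay open all the same, since 36.6% overlapped a conservative peak against 60.1% and 63.5% for a lone replicate 1 or 2, and 4.20% lay in coding exons against 0.443% of the shared peaks. What accounts for the gap stays open, and no biological explanation was tested.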

How the results depend on the processing

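The rotation of gene lists, the lists of peaks with a signal of 60 or more, the alternatives for the other motifs, the following of motifs and lists that passed under any alternative, and the replicate left out for peaks of a lone replicate were tests chosen after the results were seen. No paired analysis was possible because the design held 1 group only. Tested values counted as kept when they held their direction and side of the threshold. Untested values did so when they moved by less than their spread or, for counts of calls or peaks, stayed within a set factor. Over all alternatives, 71 values of the main results were kept, 8 moved and 10 turned in direction. Of the values for single genes, motifs and lists, 695 were kept, 344 moved, 20 lost and 17 gained a call, and 19 turned. For peaks at single genes only the set factor applied. The promoter share lay between 38.5% (200 bp) and 59.5% (1000 bp) and stayed above its background in every alternative, and sharing lay between 45.0% (reciprocal overlap) and 69.7% (without replicate 3). The calls for ribosomal protein, cuticle protein and chemoreceptor genes held in all alternatives run, and 93 of 99 named genes had a peak in all 9 other peak lists. The exceptions were CG13323 and ci (0 lists), hry (7), wg (6), odd (5) and rasp (5). That so many genes kept a peak says little, since most were named for their strong conservative peaks. Some of the other lists are parts of the conservative list, and the series-wide lists held 70.4% to 87.7% of its peaks unchanged.

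Peaks per replicate moved to 4237 at the maximum score and the correlation to 0.602 over all candidates. The share with the Ci site turned against its flanks in series-wide list 3 (0.144%) and away from promoters (0.231%). Its ratio to the flanks rose from 1.25 to 5 without replicate 1, on 5 summits and 1 flank. Its relation to signal turned to 0.00482 in series-wide list 3, 0.0134 in the 4215 strongest peaks, 0.0223 in peaks called in all 3 replicates and 0.0164 to 0.0262 with a replicate left out, each without passing the test. Motif calls numbered 5 with 50 bp windows and 6 away from promoters instead of 10, and list calls 5 instead of 3 under rotation, which does not match on territory length. The ci window turned against its background median at 40 kb (0.667) and without replicate 1 (1.5), with 0.5 to 2 over the replicates left out. Peaks of a lone replicate rose to 29.2% to 33.3% with a replicate left out, because they then need 1 missing partner only. Their promoter share turned to 50.6% in replicate 1 and 51.5% in replicate 2 by summit distance. Away from promoters, where only the flanks could lie at promoters, DREF (0.415%), Ohler motif 1 (0.277%) and the initiator (17.0%) turned. With a replicate left out the homeobox site (12.02% to 13.8%) and the Caudal site (18.6% to 20.6%, turned without replicate 1 at 20.6% and without replicate 2 at 20.4%) did so. Among motifs not called, GATA turned without replicate 3 (14.8%, with 14.8% to 15.7% over the replicates left out), Mad/Brinker without replicates 1 and 2 (8.20% and 8.46%, with 8.20% to 9.24% over the replicates left out) and Grainyhead without replicates 1, 2 and 3 (0.185%, 0.195% and 0.351%). Zelda (1.27%) and AP-1 (2.24%) turned away from promoters, and AP-1 also against GC-matched positions (2.03%), where it passed. The TATA box gained a call without each replicate (26.5% to 29.6%), against GC-matched positions and among peaks with a signal of 60 or more (23.6%), and 3 motifs and 17 lists passed in no setting. For all of these but the peaks of a lone replicate the cause was not tested. Peak lists with a replicate left out also held fewer and differently chosen peaks than the conservative list, so changes there need not come from that replicate. With depth unknown, its effect on weak peaks could not be measured.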

Other observations

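All tests in this part were chosen after the results were seen.

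Exact Gli-type sites numbered 1243 in the 7 main chromosome sequences, and 16 of them (1.29%) lay within 100 bp of a conservative summit. The share that random placement would give was not computed, so this count shows no preference of the peaks for such sites. Only 2 groups of at least 3 such sites with gaps of at most 100 bp were found. The group upstream of ptc (2R:8648891–8649022) had its nearest summit 20 bp away, and the other, nearest to a TSS of CG32651 (X:12404100–12404138), had its nearest summit 50427 bp away. In the territory of ptc, which takes in part of a neighbouring gene, 6 of 18 peaks had a site with at most 1 mismatch, among them the 2 peaks with an exact site. Peaks over the whole Hedgehog pathway list numbered 117 against 56.9 ± 12.8 in matched lists (permutation p = 2.00e-04, the smallest the draws can give, adjusted p = 8.00e-04 over 4 such tests). The total did not pass without ptc and rdx, at 77 against 50.3 ± 11.8 (permutation p = 0.0458, adjusted p = 0.0859). Over the Hedgehog target list it did not pass either, at 64 against 40.6 ± 11.2 (permutation p = 0.0644, adjusted p = 0.0859), nor without ptc and rdx, where it lay below the matched mean, at 24 against 34.1 ± 10.3 (permutation p = 0.338, adjusted p = 0.338). Totals without ptc and rdx are biased downwards, since these genes were left out for their high counts while matched lists kept theirs. They do not show whether the rest of either list carries more peaks.

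Several 8-mers were more frequent at summits than at flanks. The 8-mer TATCGATA, the core of the DREF site, lay at 258 summits and 43 flanks. CACTGAGA lay at 239 and 50, GGTCACAC, within Ohler motif 1, at 250 and 56, and CACTGTGC at 303 and 108. Base composition at the summit itself changed with signal: within 40 bp of the summit GC content was 35.8% in the 2108 strongest peaks and 46.3% in the 2107 weakest, against 43.0% and 42.2% at 160 to 240 bp. In the strongest peaks, GAGA sites numbered 65 within 40 bp and 309 between 40 and 120 bp of the summit, or 0.381 and 0.916 per kb and peak. In the other 3 classes, by falling signal, the rates were 1.02 and 1.22, 1.28 and 1.11, and 0.926 and 1.19, so that the gap was smaller and in 1 class ran the other way. The dip was not particular to GAGA sites. In the strongest peaks the rates were 0.433 and 0.682 for the E-box and 0.0410 and 0.119 for Su(H). The TATA box (2.51 and 1.76) and the homeobox site (0.984 and 0.718) ran the other way there.

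Gene territories with the most conservative peaks were those of kirre (36 in 404 kb), CG1677 (24 in 135 kb) and rdx (22 in 75.0 kb). Raf held 21 in 58.4 kb, and CHES-1-like 20 in 37.0 kb. Of 690 conservative peaks with a signal under 60, 469 (68.0%) had a stronger candidate within 350 bp, against 1.03% of the 7741 others.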
